A study of Mus musculus with 12 samples.

How the data were processed

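Total RNA from hyperplastic mammary glands of female FVB/N mice was sequenced as 12 libraries from the MIC model, which carries a doxycycline-inducible polyoma middle T oncogene together with Cre recombinase in the mammary epithelium. Doxycycline was given in the drinking water at 2 mg/ml, and the sample titles carry the time 2 wk. The labels put 4 libraries in each of 3 groups, named MIC WT, MIC Stat3 ko and MIC Chi3l1 ko, and give no batch, litter or pairing. The labels do not state exactly what separates the 4 samples of a group, so p-values here measure the spread between these samples. Libraries are written as WT 1 to WT 4, Stat3 ko 1 to Stat3 ko 4 and Chi3l1 ko 1 to Chi3l1 ko 4, in the order of the labels.

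The submitters' processing notes name Trimmomatic, STAR, HTSeq, edgeR and limma and the builds GRCm38 and mm10, without versions or roles. The authors deposited a table of FPKM (fragments scaled to gene length and library size) for 54532 genes in all 12 libraries, with the gene length in bases and the coordinates of each gene. The deposited comparison tables give raw counts per gene, the authors' log2 fold change and the authors' unadjusted and adjusted p-values, for genes with an unadjusted p under 0.05 only. The deposited FPKM multiplied by gene length gave whole counts, within 0.001 read, once a single total per library was solved from the deposited counts. Of 55832 deposited counts compared with the recovered ones, 0 differed. The recovered totals ran from 16217143 to 22607123 counts per library, and the total behind the FPKM scaling was 0.926 to 1.14 times the recovered total. Of the Ensembl identifiers, 54409 were found in the GENCODE annotation of GRCm38, and 98.3% of genes had the same coordinates there. A spreadsheet had turned 27 gene names into dates, which were restored through their identifiers.

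The design assumed FPKM, a normalised unit, before the data were examined, and that test was kept. Values were taken as log2(FPKM + 1), so every fold change of the own fits is on the log2(FPKM + 1) scale, which shrinks changes of genes near 0. Genes with at least 1 FPKM in at least 4 of the 12 libraries were tested, 13643 in all. limma 3.58.1 with an intensity trend was fitted to the 3 group means in R 4.3.3, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of fold changes are limma's moderated standard errors (SE), from a spread per gene that the 3 groups share. Levels are given as mean ± SD over 4 libraries. The levels of the targeted genes were also compared by an exact two-sided permutation test of 4 against 4 values.

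Before the data were examined, 40 gene lists were fixed, and the 38 with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. The same test with an estimated correlation and fry, which tests whether the members of a list move on balance in 1 direction, stand beside it. A count of called members is given over all tested genes and adjusted over the list alone. The genes named below follow a rule fixed at the same time. It takes the targeted genes, the 8 largest called rises and falls without overlap between groups (5 for the contrast of the knockouts), up to 4 members with the lowest adjusted p from each list that passed or had 3 called members, and 2 members of each list on STAT3, neutrophils and T cells in any case. Genes outside this rule are marked as chosen after their values were seen.

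The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, array weights, a fit of only the compared groups, and leaving out each library in turn. Alternatives added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered counts, and leaving out the 3 libraries with over 2% mitochondrial counts. All 35 splits of 8 libraries into 4 and 4 were refitted for each comparison, with the 4 libraries of the other group kept in the fit. On simulated data with known changes in this design, limma recovered 0 of 50 genes with a 1.5-fold change, 42.6% with a 2-fold change and 84.8% with a 4-fold change for Stat3 ko against WT, and 4.08%, 28.0% and 75.5% for Chi3l1 ko against WT, so nearly all 1.5-fold changes were missed there. The simulated groups had the same spread per gene. Real Stat3 ko libraries differed more from each other than WT ones did, so these rates may not hold there. In that simulation 0 of 40 random lists were called. Its genes were drawn independently, so it cannot show how often camera calls lists of correlated genes. The estimated correlation of the real T cell markers, for example, was 0.949. Tables were prepared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9. Counting intervals and floors cover counting error only.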

Results

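RNA sequencing measured gene expression in the hyperplastic mammary glands of MIC mice, in which doxycycline switches on polyoma middle T and Cre recombinase in the mammary epithelium. The series asks how Chi3l1, a secreted chitinase-like protein, relates to neutrophil extracellular traps and to T cells in breast tumours. It holds 4 WT, 4 Stat3 ko and 4 Chi3l1 ko libraries, with doxycycline in the drinking water and titles that carry 2 wk. The libraries held 16217143 to 22607123 gene counts, with a median of 17861400. Group means were 18031800 ± 2198170 counts in WT, 17665400 ± 723331 in Stat3 ko and 19754600 ± 2853080 in Chi3l1 ko (SD, n = 4). Genes encoded in the mitochondrial genome took 1.17% ± 0.233 of counts in WT, 2.80% ± 1.62 in Stat3 ko and 1.52% ± 0.529 in Chi3l1 ko. The share was 4.79% in Stat3 ko 1, 3.37% in Stat3 ko 2 and 2.22% in Chi3l1 ko 2. The first 3 principal components held 49.0%, 17.6% and 12.3% of the variance.

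The targeted genes were read first. Stat3, a transcription factor downstream of cytokine receptors (ENSMUSG00000004040, GRCm38 chromosome 11, 100885098 to 100939540, minus strand), stood at 48.0 ± 1.93 FPKM in WT and 15.8 ± 3.04 in Stat3 ko (SD, n = 4). The Stat3 ko libraries held 18.7, 17.8, 14.3 and 12.2 FPKM, a mean of 32.9% of WT, and the WT libraries held 49.6, 49.7, 46.2 and 46.4. Chi3l1 ko libraries held 50.01 ± 2.67 FPKM of Stat3. Chi3l1, listed under its older mouse symbol Chil1 (ENSMUSG00000064246, GRCm38 chromosome 1, 134182176 to 134190181, plus strand), stood at 151 ± 46.3 FPKM in WT, with 125, 212, 160 and 107 in the 4 libraries. In Chi3l1 ko, Chil1 had 1, 2, 0 and 0 counts, 3 of 79018300 in all. This is 0.0380 CPM (counts scaled to library size) (95% Clopper-Pearson interval 0.00783 to 0.111), against 469 CPM in WT. In Stat3 ko, Chil1 stood at 11.7 ± 5.33 FPKM (17.6, 4.92, 10.8 and 13.6), or 7.76% of WT.

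Stat3 fell by 1.56 ± 0.12 in Stat3 ko on the log2(FPKM + 1) scale (SE, limma adjusted p = 5.6e-05). Chil1 fell by 3.65 ± 0.31 in Stat3 ko (adjusted p = 6.9e-05), and in Chi3l1 ko it fell by 7.18 ± 0.31 (adjusted p = 1.1e-06). With Chil1 at 0 to 2 counts in Chi3l1 ko, the size of that fall depends on the scale and on the value added: it was −10.36 with a pseudocount of 0.1 and −13.31 with edgeR. The exact permutation p was 0.0286 for each of these 3 comparisons, the smallest that 4 against 4 libraries can give. Stat3 differed between Chi3l1 ko and WT by 0.06 ± 0.12, which did not pass. The labels do not give the alleles, so which part of either transcript is removed was not examined.

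**Figure D1:**
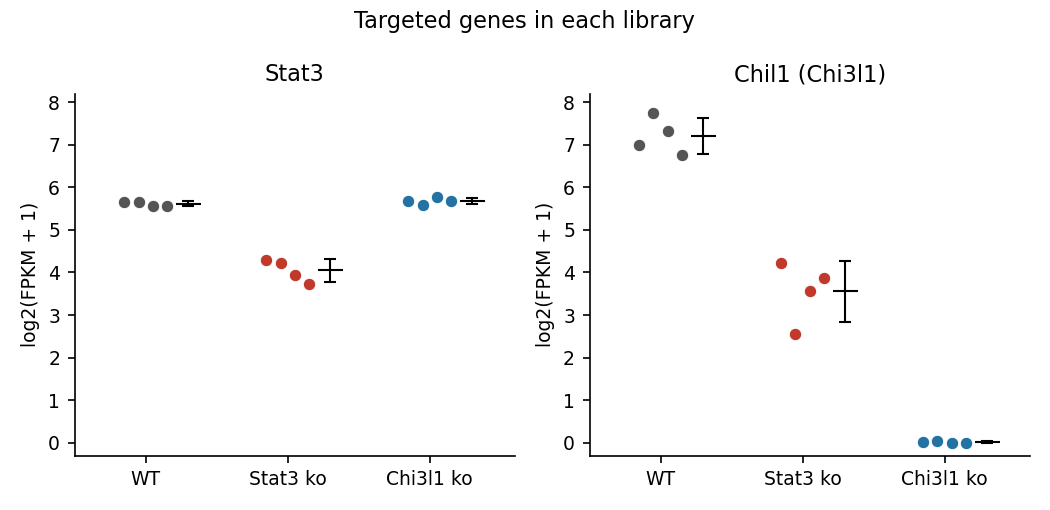
Levels of Stat3 (left) and Chil1, the gene of Chi3l1 (right), as log2(FPKM + 1) on the vertical axis, with 1 point per library and, beside the points, the mean and SD of each group of 4. Stat3 is lower in Stat3 ko, at a mean of 15.8 FPKM against 48.0 in WT, and Chil1 is lower in both knockouts, at 11.7 FPKM in Stat3 ko and 0.0117 in Chi3l1 ko against 151 in WT.

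Stat3 ko was compared with WT to see which genes depend on Stat3 in the hyperplastic gland. The falls were led by secreted acute phase and milk proteins. The serum amyloid genes Saa1 and Saa2 fell by 5.39 ± 0.31 and 5.11 ± 0.29 (adjusted p = 5.6e-06 for both, n = 4 per group), and since they are near-identical paralogs the split of reads between them is uncertain. Spp1 (osteopontin) fell by 4.99 ± 0.44, Clca3a2 by 4.69 ± 0.45, the whey acidic protein gene Wap by 3.95 ± 0.33 and Lalba (alpha-lactalbumin) by 3.60 ± 0.20. Csn1s1, a casein gene, fell by 3.80 ± 0.87, a call that ended without WT 1 (adjusted p = 0.0512) or WT 3 (0.0516) and without the libraries with over 2% mitochondrial counts (0.105).

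Among STAT3 target genes, 9 of 25 fell and 2 rose (10 and 3 adjusted over the list alone), with a median of −0.32. Lcn2, which encodes the iron-binding lipocalin 2, fell by 3.12 ± 0.31, the immediate-early gene Fos by 1.93 ± 0.15, Lrg1 by 1.41 ± 0.15 and the oncostatin M receptor gene Osmr by 1.35 ± 0.15. Of 13 acute phase genes, 6 fell and 0 rose (6 and 3 adjusted over the list alone), among them ceruloplasmin (Cp), which fell by 1.83 ± 0.18. The median of that list was −0.57. Camera called both lists lower, at adjusted p = 0.0049 for STAT3 targets and 0.021 for acute phase genes. The values were adjusted p = 0.16 and adjusted p = 0.44 with an estimated correlation, and the acute phase call ended without Stat3 ko 4 (0.0660).

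Neutrophil genes went both ways, among the part of each list that was tested. Of 24 listed neutrophil markers 9 were tested, and of these 3 fell and 1 rose (4 and 1 adjusted over the list alone). S100a8, a calcium-binding protein abundant in neutrophils, fell by 2.81 ± 0.40 (adjusted p = 0.0021). Prtn3 (proteinase 3) fell by 1.37 ± 0.26, and Padi4, the enzyme that citrullinates histones in extracellular traps, fell by 1.18 ± 0.23 (adjusted p = 0.0099). The matrix protease gene Mmp9 rose by 0.86 ± 0.21, a call that ended without WT 1 (0.0815) or WT 4 (0.0699). The list's median was 0.09 while its mean was −0.43, and camera gave the direction down with adjusted p = 0.43, while fry called the list lower (adjusted p = 0.029). Of 15 listed components of neutrophil extracellular traps 10 were tested. Among these, 6 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of 0.61 and adjusted p = 0.096. Prtn3 and Padi4 were the falls, and Ncf4, a subunit of the phagocyte oxidase that other myeloid cells also express, rose by 0.89 ± 0.21, a call that ended without WT 1 (0.0625), WT 3 (0.0543) or WT 4 (0.0634). Of 12 listed neutrophil-recruiting cytokines 3 were tested. Among these, the chemokine gene Cxcl1 fell by 1.24 ± 0.14 and Tnf rose by 1.02 ± 0.29 (1 and 1 adjusted over the list alone). The list had a median of −0.32 and adjusted p = 0.45. The call on Tnf ended without WT 1 (0.113), WT 3 (0.0957), WT 4 (0.0906), Stat3 ko 2 (0.0939) or Stat3 ko 3 (0.0647).

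Milk genes were lower. Of 14 milk protein and alveolar genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone), with a median of −1.71. Elf5, a transcription factor of alveolar cells, fell by 1.77 ± 0.23 and Xdh (xanthine dehydrogenase) by 1.21 ± 0.16. Camera gave adjusted p = 6.4e-08 for this list, and adjusted p = 0.19 with an estimated correlation. Of 21 luminal epithelial markers, 3 fell and 1 rose (7 and 3 adjusted over the list alone), with a median of −0.71, and Muc1 fell by 1.69 ± 0.27. The camera value was adjusted p = 0.049 (adjusted p = 0.61 with an estimated correlation), and this call ended without Stat3 ko 1 (0.0518), Stat3 ko 2 (0.460), WT 1 (0.0544) or WT 4 (0.132). A set of 10 general epithelial genes such as Krt8 and Epcam, chosen after its values were seen, had a median of −0.81, with Elf3 called, a call that ended without WT 1 (0.0653) or WT 4 (0.0599). Among 9 basal and myoepithelial markers none was called (3 rises adjusted over the list alone), with a median of 0.00 and adjusted p = 0.50. Of 19 glycolysis and hypoxia genes, 6 fell and 1 rose (6 and 4 adjusted over the list alone). The hypoxia-responsive gene Ndrg1 fell by 1.93 ± 0.16 and the phosphofructokinase gene Pfkl by 0.66 ± 0.08, while the list did not pass (median −0.08, mean 0.0015, direction down, adjusted p = 0.30) with camera and fry called it lower (adjusted p = 0.0022). Of 12 epithelial-mesenchymal transition genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone), with a median of 0.45 and adjusted p = 0.099.

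Lymphocyte, dendritic and MHC class II genes were higher in Stat3 ko. All 17 tested T cell markers were positive, with a median of 1.70. Of these, 4 were called over all genes and 17 adjusted over the list alone. Cd8b1, a chain of the CD8 co-receptor, rose by 1.98 ± 0.48, a call that ended without WT 1 (0.0657), WT 3 (0.0583) or WT 4 (0.0678). Of 10 cytotoxic lymphocyte and NK cell markers, 6 rose (9 adjusted over the list alone), with a median of 0.94. The chemokine gene Ccl5 rose by 2.26 ± 0.41 (adjusted p = 0.0077). The NK receptor genes Ncr1 and Klrk1 rose by 1.25 ± 0.27 and 0.66 ± 0.14, calls that ended without WT 1 (0.0540 and 0.0523). B cell and plasma cell markers had a median of 2.46, and 2 of 10 rose (8 adjusted over the list alone), including Ighm at 2.72 ± 0.60, which ended without WT 1 (0.0592) or WT 4 (0.0514). Camera gave adjusted p = 5.6e-07 for T cell, 1.9e-05 for cytotoxic and 0.00012 for B cell markers. With an estimated correlation these were adjusted p = 0.48, adjusted p = 0.26 and adjusted p = 0.48. The libraries did not contribute alike: the mean log2(FPKM + 1) of T cell markers was 2.44, 5.10, 4.29 and 1.97 in Stat3 ko 1 to 4, and that of B cell markers was 4.04, 6.85, 5.54 and 2.05. WT 2, at 2.24 and 3.13, stood above Stat3 ko 4 in both. With the B cell level of each library in the model, a test chosen after the values were seen, the mean difference of T cell markers was 0.11 ± 0.36 (SE), against 1.78 ± 0.63 without it, while the cytotoxic list (0.63 ± 0.20, camera adjusted p = 0.00072) and the dendritic list (0.62 ± 0.14, adjusted p = 5.0e-05) stayed above 0. In that fit 0 of the called T cell, cytotoxic or dendritic genes remained called.

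Dendritic cell markers rose in 8 of 12 cases (10 adjusted over the list alone), with a median of 1.21. Siglech, a receptor of plasmacytoid dendritic cells, rose by 1.36 ± 0.26, Fscn1 by 1.40 ± 0.27, Wdfy4 by 1.47 ± 0.30 and Flt3 by 0.85 ± 0.17. Camera gave this list adjusted p = 3.3e-06, and adjusted p = 0.26 with an estimated correlation. Of 20 macrophage and monocyte markers, 6 rose and 1 fell (8 and 1 adjusted over the list alone). Lyz2 rose by 1.24 ± 0.23 and Cd14, the lipopolysaccharide co-receptor, fell by 1.97 ± 0.18. That list passed (median 0.51, adjusted p = 0.00032), with adjusted p = 0.50 with an estimated correlation. Of 8 alternative macrophage activation genes, 4 rose (6 adjusted over the list alone), with a median of 1.14 and adjusted p = 0.00032, and adjusted p = 0.15 with an estimated correlation. MHC class II genes rose in 5 of 10 cases (9 adjusted over the list alone), with a median of 1.15 and adjusted p = 3.1e-05, and adjusted p = 0.44 with an estimated correlation. Of 16 MHC class I presentation genes, 3 fell (3 adjusted over the list alone), with a median of −0.06 and adjusted p = 0.38. The falls were Pdia3, Calr and Canx, and each call ended in 6 of 8 fits with a library left out.

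Of 14 T cell-recruiting chemokines and receptors, 6 rose (7 adjusted over the list alone), with a median of 0.87 and adjusted p = 0.00065, and adjusted p = 0.44 with an estimated correlation. Checkpoint and regulatory T cell genes had a median of 0.36, and Cd274, which encodes the checkpoint ligand PD-L1, was the called member of 11 at 1.23 ± 0.21 (1 adjusted over the list alone). The list's adjusted p was 0.025 (adjusted p = 0.57 with an estimated correlation), and the call ended without Stat3 ko 2 (0.113), Stat3 ko 3 (0.0765) or WT 4 (0.0793). Of 21 interferon gamma-induced genes, 20 were positive and 2 rose (2 adjusted over the list alone), with a median of 0.38 and adjusted p = 0.0017, and adjusted p = 0.57 with an estimated correlation. Type I interferon-induced genes were lower by median (−0.61), with 1 rise among 28 and 0 falls (0 and 0 adjusted over the list alone). Their adjusted p was 0.013 (adjusted p = 0.68 with an estimated correlation), and the call ended without Stat3 ko 1 (0.470) or WT 4 (0.0646). Complement genes rose in 4 of 12 cases (7 adjusted over the list alone), with Cfp (properdin) at 1.15 ± 0.17 and C1ra at 1.37 ± 0.27. Their median was 0.81 and adjusted p = 0.00032, and adjusted p = 0.44 with an estimated correlation.

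Fat genes were also higher, and unevenly between libraries. All 17 adipocyte markers were positive, with a median of 2.65 and 6 called (16 adjusted over the list alone). Pck1, a gene of glycerol and glucose synthesis, rose by 4.53 ± 1.11, a call that ended without WT 1 (0.0786), WT 3 (0.0617), WT 4 (0.0571) or Stat3 ko 2 (0.0582). Fabp4, a fatty acid carrier of adipocytes, rose by 3.31 ± 0.92 and the lipid droplet gene Plin1 by 3.28 ± 0.92. These 2 calls ended without WT 1 (0.110 and 0.111), WT 2 (0.0554 and 0.0575), WT 3 (0.0814 and 0.0837), WT 4 (0.0789 and 0.0788), Stat3 ko 1 (0.0561 and 0.0552) or Stat3 ko 2 (0.0776 and 0.0714). Cyp2e1, a cytochrome P450 gene, rose by 4.05 ± 0.85, a call that ended without WT 1 (0.0507). Camera gave adipocyte markers adjusted p = 4.5e-07, and adjusted p = 0.48 with an estimated correlation, and their mean log2(FPKM + 1) was 8.62 in Stat3 ko 1. Lipogenesis genes rose in 4 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone), with a median of 1.12 and adjusted p = 0.00076, and adjusted p = 0.53 with an estimated correlation. Brown adipocyte genes had a median of 3.36 and no called member of 6 (4 adjusted over the list alone), with adjusted p = 0.0036, and adjusted p = 0.48 with an estimated correlation. Skeletal muscle markers had a median of 1.91 and no called member of 17 (0 adjusted over the list alone). Their adjusted p was 0.046 (adjusted p = 0.68 with an estimated correlation), and the call ended without Stat3 ko 2 (0.332), Stat3 ko 4 (0.259), WT 1 (0.226) or WT 4 (0.196).

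Stromal lists rose by camera. Fibroblast and matrix genes had a median of 0.66 with 3 rises among 20 (3 adjusted over the list alone), and adjusted p = 0.0018, with adjusted p = 0.57 with an estimated correlation. Among the rises was Thy1 at 1.12 ± 0.21, a gene that T cells of mice also express, so its rise is not specific to stroma. Endothelial markers had a median of 0.82 with 3 rises among 15 (12 adjusted over the list alone) and adjusted p = 1.4e-05, with adjusted p = 0.49 with an estimated correlation. Lymphatic endothelial markers had a median of 1.49 with 1 rise among 3 (2 adjusted over the list alone) and adjusted p = 0.042, with adjusted p = 0.44 with an estimated correlation. That call ended without Stat3 ko 1 (0.0733), Stat3 ko 2 (0.0577), Stat3 ko 3 (0.0524), Stat3 ko 4 (0.0503) or WT 4 (0.0770). The 13 mitochondrially encoded genes had a median of 1.12 and 0 calls (0 adjusted over the list alone), with adjusted p = 0.00032, and adjusted p = 0.52 with an estimated correlation. The mitochondrial tRNA gene mt-Te rose by 3.46 ± 0.71. FPKM is scaled to gene length, so in such a short gene few reads can give a large value. The reads behind the mt-Te rise were not examined. Nuclear oxidative phosphorylation genes had a median of 0.61 and 0 calls among 18 (0 adjusted over the list alone), with adjusted p = 9.3e-05, and adjusted p = 0.54 with an estimated correlation. All 27 proliferation genes were negative, with a median of −0.51 and 0 calls (0 adjusted over the list alone). Their adjusted p was 0.0040 (adjusted p = 0.65 with an estimated correlation), and the call ended without Stat3 ko 1 (0.374). Lists that did not pass were immediate-early and stress genes (median −0.27, adjusted p = 0.21), ribosomal protein genes (−0.12, 0.080), erythroid genes (0.14, 0.74), Schwann cell markers (median −0.16, mean 0.0026, direction down, 0.74) and the chitinase-like family with proposed CHI3L1 receptors (−0.07, 0.43). Of these, immediate-early and stress genes had 2 falls and 1 rise, and the Schwann cell and chitinase-like lists had 1 fall each. Keratinocyte markers and replication-dependent histone genes had fewer than 3 tested members.

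**Figure D2:**
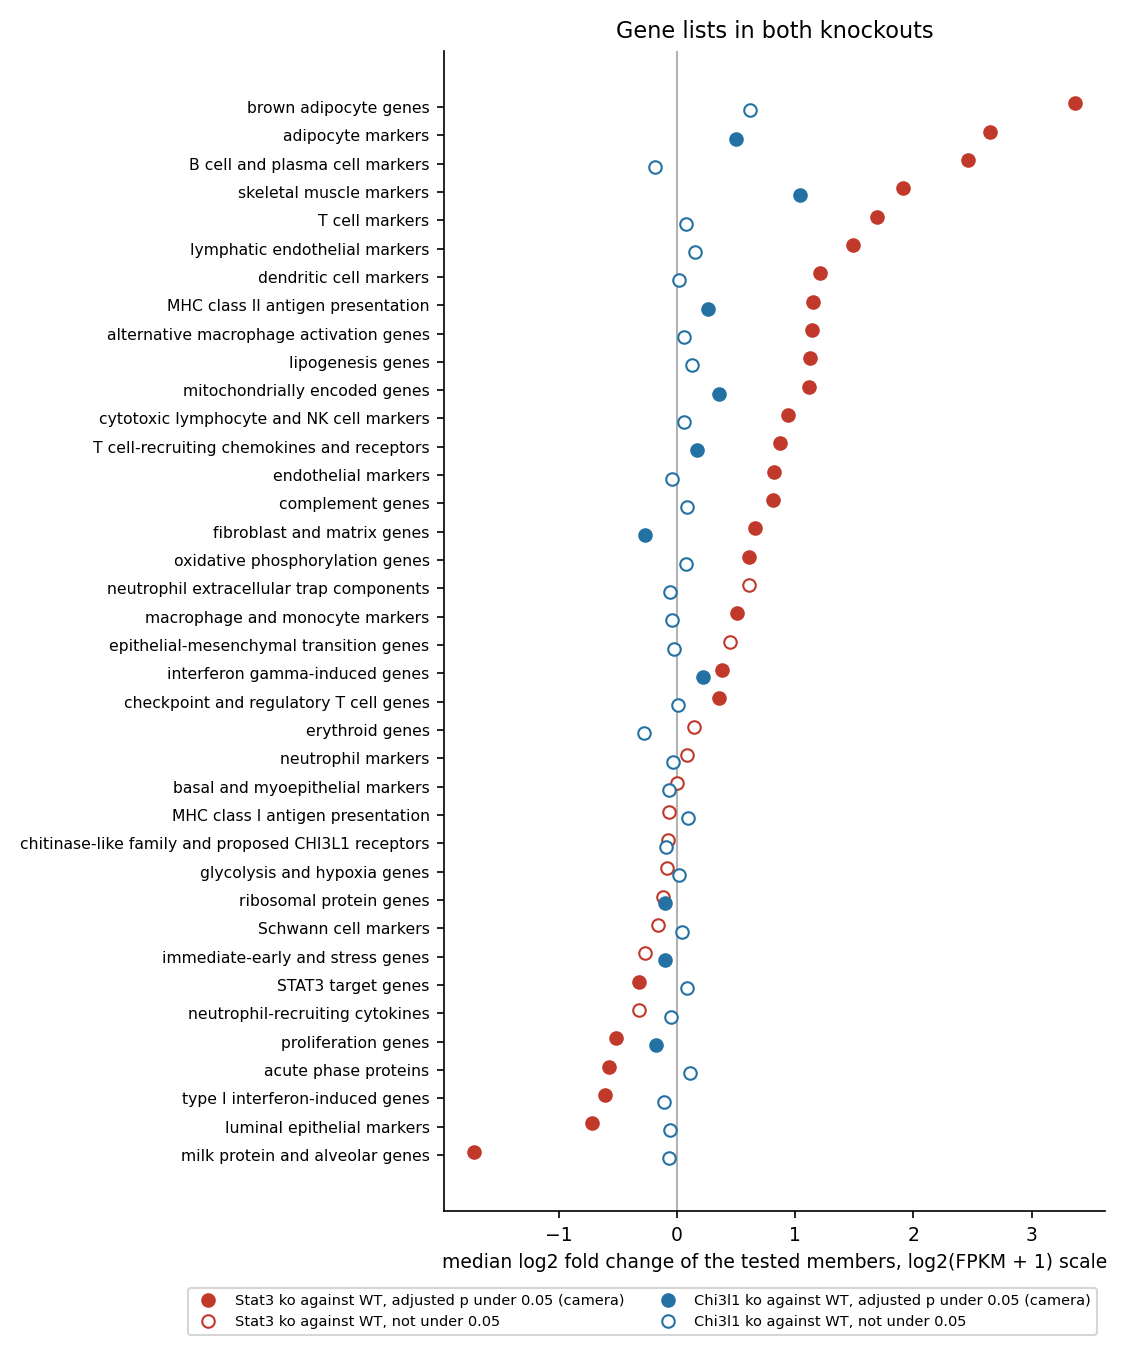
Median log2 fold change of the tested members of each of 38 gene lists, on the log2(FPKM + 1) scale, in Stat3 ko (red) and Chi3l1 ko (blue) against WT, with filled points where camera at the preset correlation gave an adjusted p under 0.05. Stat3 ko medians run from −1.71 for milk protein and alveolar genes to 3.36 for brown adipocyte genes, and Chi3l1 ko medians from −0.28 for erythroid genes to 1.04 for skeletal muscle markers. With an estimated correlation 0 lists passed in either comparison.

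In total limma called 1911 of 13643 genes in Stat3 ko, 766 higher and 1145 lower, with 4654 at an unadjusted p under 0.05. The median called rise was 0.96 and the median called fall was −0.70. The 2 groups of 4 did not overlap in 21.3% of genes, where chance gives 2.86%. Of the called genes 40.1% were higher. The share was 29.9% with a mean of at least 5 FPKM, 31.3% with quantile normalization and 45.4% with array weights. On the recovered counts it was 55.6% of 2955 with edgeR and 61.5% of 4392 with DESeq2, which tested 16446 and 31268 genes, so tool, scale and gene set changed together. The count fell to 571 without WT 1, 912 without WT 3, 766 without WT 4 and 1100 without Stat3 ko 2, and rose to 3252 without Stat3 ko 4. With only the 2 compared groups in the fit, 506 genes were called, 148 higher and 358 lower. Without the libraries with over 2% mitochondrial counts, an alternative chosen after the data were seen, 1274 genes were called (616 higher, 658 lower), 972 of them shared. That setting ended the calls on mitochondrially encoded genes (0.144) and on checkpoint, luminal, lymphatic and muscle lists, and turned proliferation (0.260) and type I interferon genes (0.529) higher without a call. Among genes named above it also ended the calls on Ccl5 (0.0518), Siglech (0.0522), Fscn1 (0.0538), Mmp9 (0.0602), Elf3 (0.0739) and Cd8b1 (0.0884). Camera called 26 of 38 lists and fry 16. Fry did not call 12 of the 26: checkpoint, macrophage, type I interferon, interferon gamma, luminal, lipogenesis, muscle, fibroblast, endothelial, proliferation, mitochondrially encoded and oxidative phosphorylation genes (adjusted p from 0.059 to 0.43). Of 96 named genes called here, 63 lost the call in at least 1 fit with a library left out and 33 kept it in every such fit.

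**Figure D3:**
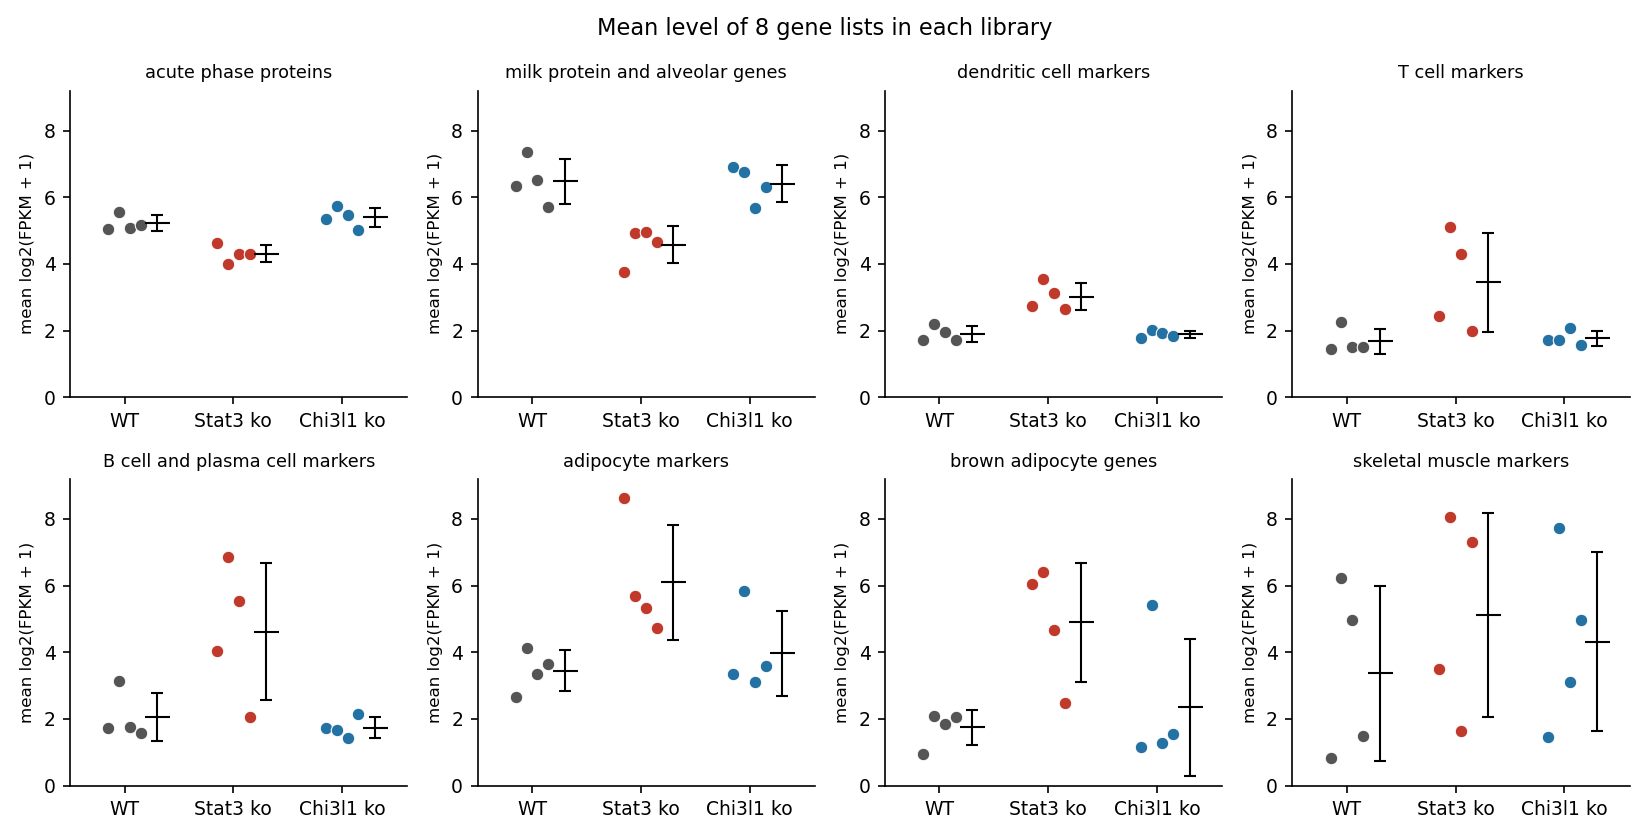
Mean log2(FPKM + 1) of the tested members of 8 gene lists, with 1 point per library and, beside the points, the mean and SD of each group of 4. Acute phase and milk genes are lower in all 4 Stat3 ko libraries, while T cell markers range from 1.97 to 5.10 within Stat3 ko, and Chi3l1 ko 2 stands above the rest of its group in adipocyte markers, at 5.84, and brown adipocyte genes, at 5.42.

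Chi3l1 ko was compared with WT to see what changes in the gland without the secreted factor itself. Chil1 was the single gene called by limma, and it fell. At an unadjusted p under 0.05 there were 222 genes, edgeR called 1 and DESeq2 called 7, and the groups did not overlap in 2.48% of genes, where chance gives 2.86%. No member of any fixed list was called over all genes. The neutrophil markers had a median of −0.04, trap components −0.06, T cell markers 0.08, cytotoxic and NK markers 0.06, STAT3 targets 0.08 and acute phase genes 0.11, with adjusted p from 0.086 to 0.90 and 0 members called adjusted over the list alone. The neutrophil and trap medians cover only the 9 of 24 and 10 of 15 listed members that were tested. Padi4 differed by −0.45 ± 0.23, Cd8a by 0.43 ± 0.44, Fos by −0.44 ± 0.15 and Gzmb, a granzyme of cytotoxic lymphocytes, by −0.59 ± 0.18 (limma adjusted p = 0.9998 for each), and none passed.

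Camera at the preset correlation called 10 lists in Chi3l1 ko, which neither an estimated correlation nor fry supported. All 21 interferon gamma-induced genes were positive, with a median of 0.22, and MHC class II genes had a median of 0.26. T cell-recruiting chemokines had a median of 0.17, with Ccl3 at 0.59 ± 0.23. All 27 proliferation genes were negative (median −0.18) and so were all 20 ribosomal protein genes (−0.10). Camera gave adjusted p = 0.00033 for interferon gamma-induced and ribosomal protein genes, 0.0059 for MHC class II and proliferation genes, and 0.037 for the chemokines. It also called adipocyte markers (median 0.50, 0.0089), mitochondrially encoded genes (0.36, 0.0089) and skeletal muscle markers (1.04, 0.037) higher, and immediate-early and stress genes (−0.10, 0.011) and fibroblast and matrix genes (−0.27, 0.033) lower. Each of these 10 lists had adjusted p = 0.96 with an estimated correlation, and fry called 0 lists. Adjusted over the list alone, the single member called was the phosphatase gene Dusp1, at −0.88 ± 0.23.

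Of these 10 calls, that on ribosomal protein genes held with every library left out in turn. The interferon gamma call ended without Chi3l1 ko 3 (0.268) or WT 3 (0.397). MHC class II ended without Chi3l1 ko 3 (0.213), WT 1 (0.0947) or WT 4 (0.0903), and proliferation without WT 1 (0.0594) or WT 4 (0.312). The chemokine call ended without Chi3l1 ko 1 (0.0721), Chi3l1 ko 2 (0.0668), Chi3l1 ko 3 (0.309), WT 1 (0.228), WT 3 (0.397) or WT 4 (0.0640). Adipocyte markers ended without WT 1 (0.263) and turned lower without Chi3l1 ko 2 (0.796). Muscle markers also turned lower without Chi3l1 ko 2 (0.796) and ended without Chi3l1 ko 4 (0.149), WT 1 (0.872) or WT 4 (0.649). The mitochondrial call ended without Chi3l1 ko 2 (0.529) or WT 1 (0.166), and the immediate-early call without Chi3l1 ko 2 (0.0993) or WT 1 (0.183). Fibroblast genes ended without Chi3l1 ko 1 (0.608), Chi3l1 ko 3 (0.180) or Chi3l1 ko 4 (0.0589) and turned higher without WT 3 (0.625). The median, mean and camera direction differed in sign for 7 lists that did not pass, among them milk genes (median −0.07, direction up) and neutrophil-recruiting cytokines (median −0.05, mean 0.11).

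The contrast of Stat3 ko with Chi3l1 ko tests the difference between both knockouts directly. Saa1 and Saa2 were lower in Stat3 ko by −5.89 ± 0.31 and −5.59 ± 0.29 (adjusted p = 2.9e-06 for both), Spp1 by −4.88 ± 0.44 and Wap by −4.07 ± 0.33. Chil1 was higher in Stat3 ko by 3.54 ± 0.31, a size that depends on the scale and the value added, as Chi3l1 ko held 3 Chil1 counts in all. Of STAT3 targets 9 of 25 were lower and 1 higher (10 and 2 adjusted over the list alone), and of milk genes 10 of 14 were lower (11 adjusted over the list alone). The camera values were adjusted p = 0.0035 and 4.0e-08, and adjusted p = 0.12 and adjusted p = 0.18 with an estimated correlation. S100a8 was lower by −2.66 ± 0.40, and Ccl5 was higher by 2.13 ± 0.41, Fscn1 by 1.53 ± 0.27, Lyz2 by 1.22 ± 0.23 and the immunoglobulin segment Ighd4-1 by 3.92 ± 0.80. FPKM is scaled to gene length, so few reads in a short gene segment can give a large value. The reads behind the Ighd4-1 rise were not examined. The call on Ccl5 ended without the libraries with over 2% mitochondrial counts (0.0736). Dendritic cell markers were higher in 8 of 12 cases (11 adjusted over the list alone; adjusted p = 3.0e-06, and adjusted p = 0.22 with an estimated correlation). T cell markers had 1 called member of 17 (16 adjusted over the list alone) and a median of 1.63, with adjusted p = 2.1e-06, and adjusted p = 0.48 with an estimated correlation.

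This contrast called 1799 genes, 708 higher and 1091 lower in Stat3 ko, with 4329 at an unadjusted p under 0.05 and 17.0% of genes without overlap. Of the called genes 39.4% were higher, against 26.8% with a mean of at least 5 FPKM and, with tool, scale and gene set changed together, 51.7% of 2482 with edgeR and 60.5% of 4051 with DESeq2. The count was 1074 without Stat3 ko 2, 2890 without Stat3 ko 4, 611 without Chi3l1 ko 1, 773 without Chi3l1 ko 3 and 686 without Chi3l1 ko 4. With only the compared groups in the fit it was 505. Of 38 lists camera called 20, of which 0 passed with an estimated correlation. Among lists that did not pass, neutrophil markers (median 0.11, mean −0.32, direction down) and basal markers (median −0.16, mean 0.21, direction up) differed in sign between these measures.

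Both knockouts were measured against the same WT libraries. Across 13643 genes the 2 sets of fold changes had r = 0.329, a value across genes, which are not independent replicates. In 100 simulations of unchanged groups that share their controls, r was 0.499 on average (0.436 to 0.556). Those groups hold no changed genes, and changes in 1 knockout can lower r, so the real and simulated r are not like for like. The covariance of the fold changes was 0.0422, against a simulated mean of 0.0375 and a simulated maximum of 0.0446. With the WT libraries split so that each knockout had its own pair, the mean r of 6 splits was 0.125 (−0.200 to 0.262). Without Chi3l1 ko 2 r was −0.0537, and without WT 2 it was 0.493.

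The deposited comparison tables list 6155 genes for Stat3 ko, of which 3547 have an adjusted p under 0.05 (2314 higher and 1233 lower). Of the 2514 tested here, limma called 1727 in the same direction and 0 in the opposite one. For Chi3l1 ko the tables list 824 genes, of which 31 have an adjusted p under 0.05 (11 higher and 20 lower). Of the 28 tested here, 1 was called, Chil1. Padi4 is among the 31, with the authors' log2 fold change at −0.583 and adjusted p = 0.0169. The keratin genes Krt77, Krt1 and Krt15 are among the 20 lower, with most of their WT counts in WT 1 and WT 3. In WT 1 to 4, Krt77 had 679, 1, 1343 and 0 counts, Krt1 had 237, 1, 600 and 1, and Krt15 had 517, 13, 821 and 25. These tables were made from the same libraries, so they are not independent evidence.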

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

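All tests in this part were chosen after the results were seen, including 7 sets of covariates, of which the pan-epithelial, B cell and adipocyte levels were then used for the tests. With those 7 sets in the Stat3 ko fit, 82 to 1002 genes were called instead of 1911. For each measure the gap between the most distant of 4 libraries and its nearest neighbour was divided by the range, and a ratio above Dixon's 95% critical value marked the library as far from its group. Of 695 groups tested, 62 met this, where chance gives about 34.8 (1 in 20). Among 135 groups of depth measures, targeted genes and list levels, 12 met it (6.75 expected), and among 560 groups of 187 other named genes, 50 did (28 expected). The scan leaves out 1 named gene, by a choice made after its value was seen and for reasons unrelated to it.

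WT 2 stood high in immune genes. Its mean log2(FPKM + 1) was 2.24 for T cell markers, 2.40 for checkpoint and regulatory T cell genes, 3.13 for B cell and plasma cell markers and 5.49 for MHC class II genes. The same held on the log2(FPKM + 1) scale for Cd74 (11.23), H2-Aa (6.55), H2-DMb1 (4.49), Ciita (3.45), Cd22 (0.90), Iglc2 (3.07), Igkv1-117 (5.42), Ighd4-1 (3.72), Trbc2 (4.24), Klrd1 (2.21), Ccl4 (2.70) and Siglech (1.48). As a short gene segment, Ighd4-1 can reach such a value with few reads, and it was 0 in the rest of WT. The top 10 genes took 5.96% of counts in WT 2.

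Chi3l1 ko 2 stood high in fat and oxidative genes. Its mean log2(FPKM + 1) was 5.84 for adipocyte markers, 5.97 for lipogenesis genes, 5.42 for brown adipocyte genes and 6.80 for oxidative phosphorylation genes. Single genes were Ucp1 (6.62), Cox7a1 (6.87), Elovl3 (1.77), Slc36a2 (4.42), Fabp4 (7.94), Plin1 (5.71), Cfd (8.90), Thrsp (8.34), Vim (6.62), Ndufv1 (6.19), Sdhb (6.42), Uqcrc1 (6.64) and Ccl21a (0.64), all high, and Tgfb2 (3.64), low.

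Other libraries were far from their groups in fewer measures, given as log2(FPKM + 1). The ratio compares a gap with the range, so it can also mark a small gap. Immediate-early and stress genes in WT 1 stood at 4.35, where the rest of WT had 4.20 to 4.23. Lrg1 in Chi3l1 ko 4 stood at 7.95, where the rest of that group had 7.73 to 7.76. By contrast, Ucp1 in Chi3l1 ko 2 stood at 6.62, where the rest had 0.04 to 0.45. Stat3 ko 1 was low in neutrophil-recruiting cytokines (mean 0.90) and Gbp4 (4.20) and high in Cfd (11.82), Plin4 (8.43), Dcn (7.24), Vim (8.02) and Osmr (2.54), and Stat3 ko 2 was low in Scd2 (5.79). WT 1 was high in immediate-early and stress genes (mean 4.35) and low in Ncr1 (0.37). WT 3 was high in Ccl21a (3.69) and Adm (2.09) and low in Ltf (9.68) and Xcl1 (1.38), and WT 4 was high in Ucp1 (1.72), Uqcrc1 (6.01) and Uqcrc2 (5.86). Chi3l1 ko 1 was high in the share of counts from milk genes (1.57%) and in Btg2 (4.49). Chi3l1 ko 3 was high in Ccl5 (4.48), Cd8a (3.02), Cd8b1 (2.79), Cebpd (4.03), Hspa1a (2.82) and Ncf4 (3.63), and Chi3l1 ko 4 was high in Lrg1 (7.95) and low in Mfge8 (8.61).

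The falls in Stat3 ko might come from a lower share of epithelial cells, since 10 general epithelial genes had a median of −0.81 (SD 0.31 over genes). Their mean log2(FPKM + 1), less the mean of all 12 libraries, was −1.29 and −0.83 in Stat3 ko 1 and 2, while Stat3 ko 3 and 4 (0.05 and 0.25) lay inside the WT range of 0.04 to 0.57. With the level of those genes in the model, the mean difference of acute phase genes went from −0.91 ± 0.18 to −1.04 ± 0.23 (SE), that of milk genes from −1.90 ± 0.42 to −1.79 ± 0.56 and that of STAT3 targets from −0.47 ± 0.06 to −0.40 ± 0.07. These means lie below 0 by more than 2 SE, but the level is a noisy measure, so an incomplete correction could leave them there. In Stat3 ko 3 and 4 the mean log2(FPKM + 1) of acute phase genes was 4.29 and 4.31 (WT 5.06 to 5.56). That of milk genes was 4.97 and 4.65 (WT 5.71 to 7.35), and that of STAT3 targets 4.82 and 4.95 (WT 5.23 to 5.32). As their epithelial level lay inside the WT range, this argues against a lower general epithelial share as the whole cause there. The general set cannot show a lower share of alveolar cells alone. Camera called the 3 lists in that fit at the preset correlation (adjusted p = 0.00023, 2.9e-12 and 0.0036) but not with an estimated one (0.211, 0.146 and 0.141). Over all 1145 called falls, 285 (24.9%) were still called. The median of the 1145 went from −0.70 to −0.44. For the falls as a whole, a lower share and a loss of Stat3 within cells cannot be told apart in this fit. The genotype stays open as the biological explanation for the 3 lists, as a hypothesis found and tested on the same data.

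The rises of lymphocyte and dendritic genes may come from lymph node tissue, which a mammary gland can hold, or from a lower epithelial share. With the B cell level in the model, the mean difference of T cell markers went from 1.78 ± 0.63 to 0.11 ± 0.36 (SE, camera adjusted p = 0.34), consistent with lymph node tissue, while those of cytotoxic and NK markers (1.002 ± 0.189 to 0.63 ± 0.20, adjusted p = 0.00072) and dendritic markers (1.11 ± 0.20 to 0.62 ± 0.14, adjusted p = 5.0e-05) stayed above 0. With the epithelial level they were 1.56 ± 0.83 for T cell, 0.78 ± 0.22 for cytotoxic and 0.96 ± 0.25 for dendritic markers. Camera at the preset correlation gave adjusted p = 4.2e-06, 4.7e-05 and 3.1e-06 in that fit. The epithelial level is a noisy measure, so the cytotoxic and dendritic means above 0 cannot exclude a lower epithelial share. Stat3 ko 3 and 4 lay inside the WT range of that level. Their mean log2(FPKM + 1) of cytotoxic markers was 2.66 and 2.11 (WT 1.34 to 1.99). That of dendritic markers was 3.12 and 2.64 (WT 1.71 to 2.21). In these libraries this argues against a lower share as the whole cause, by a small margin for cytotoxic markers in Stat3 ko 4. For T cell markers a lower share cannot be told apart from other causes, as 2 SE cover 0 although camera still called the list. No single gene of these lists stayed called with either level. Ccl5 was 1.87 ± 0.50 with the epithelial level and 1.21 ± 0.36 with the B cell level, against 2.26 ± 0.41 without, and Cd8b1 was 1.62 ± 0.60 and 0.62 ± 0.30, against 1.98 ± 0.48, so the differences of these genes shrank with both levels and their errors grew with the epithelial one. With an estimated correlation camera called none of these lists in either fit (adjusted p from 0.123 to 0.871). Cytotoxic markers came to 0.46 ± 0.23 with adipocyte and B cell levels together. With the muscle level added they came to 0.47 ± 0.24, where 2 SE cover 0. The B cell level is itself higher in Stat3 ko and is a noisy measure of lymph node tissue, so a real gain of B and T cells and an incomplete correction both remain open.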

How the results depend on the processing

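The alternatives with edgeR, DESeq2 and the libraries with over 2% mitochondrial counts left out were chosen after the data were seen; the others were planned before. The levels of Stat3 and Chil1 kept their direction and their calls under every setting run, but the fall of Chil1 in Chi3l1 ko, −7.18, was −10.36 with a pseudocount of 0.1, −13.31 with edgeR and −13.56 with DESeq2, as counts of 0 to 2 leave its size to the scale and the value added. Genes called in Stat3 ko against WT were 1911, and 1149 with no filter, 506 with only the 2 groups compared, 2955 with edgeR and 4392 with DESeq2; leaving out 1 library gave 571 (without WT 1) to 3252 (without Stat3 ko 4), and also 912 without WT 3, 766 without WT 4 and 1100 without Stat3 ko 2. In Chi3l1 ko against WT the count was 1, with 2 under array weights, 7 with DESeq2 and 1 with edgeR. In Stat3 ko against Chi3l1 ko it was 1799, and 1119 with no filter, 505 with only the 2 groups compared and 4051 with DESeq2; leaving out 1 library gave 611 (without Chi3l1 ko 1) to 2890 (without Stat3 ko 4), and also 1074 without Stat3 ko 2, 773 without Chi3l1 ko 3 and 686 without Chi3l1 ko 4. No filter adjusts over 31268 genes. The fit of 2 groups has fewer libraries and takes its spread from those groups alone, while the main fit shares the spread of each gene among all groups. Stat3 ko libraries differed more from each other: the Pearson r of log2(FPKM + 1) between pairs was 0.894 to 0.947. It was 0.969 to 0.988 in WT and 0.952 to 0.990 in Chi3l1 ko. What lowered the counts in the fit of 2 groups was not tested, nor was the cause for the rest. Of the lists, 26 passed in Stat3 ko against WT, 0 with an estimated correlation and 16 with fry. In Chi3l1 ko against WT 10 passed, 0 with an estimated correlation, 0 with fry, and 3 (without WT 1) to 15 (without WT 2) with a library left out. In Stat3 ko against Chi3l1 ko 20 passed, 0 with an estimated correlation and 11 with fry. The correlation of fold changes was 0.329, and 0.125 with the WT libraries split, −0.0537 without Chi3l1 ko 2 (reversed) to 0.493 without WT 2; the cause was not tested. Results for named genes kept their side of the threshold in 4330 settings, lost it in 714 and gained it in 158, and 0 results called in the main fit reversed. A change of sign in a result that the main fit did not call was counted as kept, whether or not the setting called it. Of 293 such results, 229 had a value with a mean of at least 5 FPKM, 291 with edgeR and 287 with DESeq2. Without the libraries with over 2% mitochondrial counts 1274, 1 and 1575 genes were called in the 3 comparisons. No paired analysis was possible because the labels give no shared replicate numbers. At these depths 3 counts in a library are 0.133 to 0.185 CPM, and 23264 genes had no count in any library.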

Other observations

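All tests in this part on clock genes and keratinocyte markers were chosen after their values were seen, and so were the counts over splits. Genes of the circadian clock differed between Stat3 ko and WT. Dbp, a transcription factor driven by the clock, rose by 2.98 ± 0.49 (SE, n = 4 per group, limma adjusted p = 0.0049), Tef by 1.92 ± 0.39 and Nr1d1, a repressor of the core loop, by 1.90 ± 0.42. Npas2, of the opposite arm, fell by 1.11 ± 0.15 (adjusted p = 0.0018) and Nfil3 by 0.61 ± 0.16, while Hlf and Bhlhe41, counted with the first arm, fell by 0.62 ± 0.14 and 1.30 ± 0.39. Of 14 tested clock genes 8 were called, 6 of them with the sign that a shift in time gives.

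A different time of day at collection is a candidate explanation, and more fat tissue, where clock output genes are abundant, is another. The difference between the arms was 1.27 ± 0.32 in Stat3 ko against WT (exact permutation p = 0.0286, the smallest possible), and 0.58 ± 0.32 with the adipocyte level in the model. In Chi3l1 ko against WT it was 0.57 ± 0.32 (exact permutation p = 0.0571), and 0.43 ± 0.23 with the adipocyte level, with 0 of 14 clock genes called by limma. The authors' table for Chi3l1 ko has 2 of them at an adjusted p under 0.05, both higher: Per3 (log2 fold change 1.05, adjusted p = 7.1e-08, 214 to 326 counts in WT and 528 to 595 in Chi3l1 ko) and Tef (1.21, adjusted p = 0.017), where limma gave 0.69 ± 0.30 and 0.95 ± 0.39. In each comparison 11 of 14 genes (78.6%) had the sign of a shift, under the 80% set for calling it a shift, and neither explanation can be told apart from an effect of genotype, since the labels give no collection times. The first form of the rule would have counted the overlap of Chi3l1 ko with WT against a time shift. It was rewritten after that value was seen, because a p that misses the threshold excludes nothing, so this reading is weaker than that of a rule fixed in advance.

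Keratinocyte markers, most of them below the filter, were uneven among WT libraries. Summed over 10 genes, WT 1 had 2955 counts and WT 3 had 5377, where the other libraries had 330 to 803. Krt77 had 679 and 1343 counts in these libraries and 0 to 2 in the others. In 8 of 10 genes WT 1 and WT 3 were the highest pair. Of the rest, Krt2 had 0 counts in every library, and Sbsn was highest in Chi3l1 ko 1 and WT 3.

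The 8 libraries of each comparison were split into 4 and 4 in all 35 ways, each fitted with the remaining group of 4 kept in the model. For Stat3 ko against WT 1 split, the real one, gave as many genes as 1911, with 4 as the highest of the others. Ranking first of 35 is the most that these splits can show. The other splits mix the genotypes, which can add to their spread and lower their counts, so the gap does not measure the strength of the result. For Chi3l1 ko against WT 2 of 35 splits gave the real count of 1, and the highest other was also 1, so chance cannot be excluded for the count. For Stat3 ko against Chi3l1 ko 1 split, the real one, gave as many as 1799, and the highest other gave 266, with the same limits as for Stat3 ko against WT.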
